A study of Arabidopsis thaliana with 12 samples.

How the data were processed

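The series compared ga-1 and gid1 seedlings with and without GA3. Groups were taken from the sample titles, with the replicate numbers given there. A free-text description field names GA3 for the mock samples too, which conflicts with the titles and source names, and the titles were followed. Per the labels' protocols, RNA was extracted from about 80 mg of seedlings with an RNeasy kit, and about 1 µg was amplified and biotin-labelled.

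The deposited values are intensities, MAS5 signals on a linear scale per the submitters' processing notes, which give no version. On each array the mean of the values without the lowest and highest 2% was 500.0, so each array had been scaled to a common level. Scanner files and detection calls were not used here.

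Values were floored at 1 and taken to log2. Array medians lay between 7.41 and 7.56 on the log2 scale, a span under the limit of 0.5 set for further centring, so the authors' scaling was kept. The 64 control probe sets were left out, and probe sets with a mean log2 value below the 30th percentile (5.55) were removed, which left 15922 of 22746. In R 4.3.3, limma 3.58.1 was fitted to the 4 group means over all 12 arrays (lmFit, then eBayes with an intensity trend), with Benjamini-Hochberg adjustment and a threshold of 0.05. Contrasts were GA3 against mock in each mutant, the difference of these responses (ga-1 minus gid1), gid1 against ga-1 in mock, and the pooled mutant difference. Gene lists were tested with camera (preset correlation 0.01, and estimated) and fry. The 3'/5' log2 differences of the actin, GAPDH and ubiquitin control probe sets gave exact permutation p of 0.3 or more between groups, two-sided, where 3 against 3 arrays allow no p under 0.1, so a difference could not be shown. That of actin was 2.18 ± 0.15 in ga-1 mock and 2.50 ± 0.38 (SD, n = 3) in ga-1 with GA3.

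Probe sets were named through the platform annotation and a TAIR10.1 gene table. Of all probe sets, 13513 had 1 symbol, 503 had several and 8794 were not listed, and 8770 of those tested had 1 symbol. Probe sets without a single symbol are called unnamed. Of the 26 gene lists, with 350 entries, 51 entries had a named probe set and 46 were tested, so 7 lists had at least 3 tested genes. The fixed list of seed storage genes had none.

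The rule for named genes, set before the data were examined, took per comparison the 10 largest rises and 10 largest falls among calls with no overlap between arrays and 1 gene per probe set (within ga-1 for the difference), the 5 smallest p each way where nothing was called, up to 4 called members of each list or 2 by smallest p, and the targeted genes. AT3G02480 is named for the difference of responses outside the rule, since its ga-1 arrays overlap, and was chosen after its values were seen, as were ICL and the other seed markers.

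On arrays simulated from the real means and spreads with 200 changed probe sets among 15922, the ga-1 comparison recovered 66 of 100 probe sets changed by 1 on the log2 scale and 94 of 100 changed by 2. The gid1 comparison recovered 63 and 95, and the difference of responses, with the change in ga-1, recovered 36 and 83. False calls made up 7.5% of the calls in ga-1, 7.1% in gid1 and 4.0% in the difference. The simulated noise was drawn independently for each probe set, so correlation between genes was not simulated. Alternatives were another scaling (quantile, median centring), no or a stricter low-value filter, log2(value + 32), no trend, the compared groups alone, array weights, the replicate number as a block, each array left out, a 2-fold limit and an adjusted p under 0.01. The 2-fold limit and the adjusted p under 0.01 were applied to counts of calls and to the set that fell in ga-1. They were not applied to single genes or lists. A seed-marker covariate was added after seeing the data.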

Results

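Transcript levels were measured on Affymetrix ATH1 arrays in light-grown Arabidopsis seedlings, 7 days old, of 2 mutants. The ga-1 mutant (SALK_109115) does not make the growth hormone gibberellin (GA) in normal amounts. The gid1a-1 gid1b-1 gid1c-2 mutant, called gid1 here, carries mutations in all of the GID1 genes, which encode the soluble GA receptors. Seedlings of each mutant were mock-treated or given 100 µM of the gibberellin GA3 for 1 h, which makes 4 groups of 3 arrays, described by the submitters as independent biological replicates. The 12 arrays hold MAS5 signals for 22810 probe sets, with array medians between 169.7 and 188.8 and values from 0.1 to 50057.9. The number of arrays, 3 per group, limits the precision of every comparison. Correlations between arrays on the log2 scale ran from 0.943 to 0.980, and replicate 2 of ga-1 with GA3 had the lowest mean correlation with its own group, 0.956.

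The mutated receptor genes were examined first. GID1A (AT3G05120) had a signal of 679 ± 35.9 (SD, n = 3) in ga-1 mock arrays and 60.7 ± 15.9 (SD, n = 3) in gid1 mock arrays, a log2 difference of -3.52 (limma adjusted p = 2.4e-07). GID1B (AT3G63010) had 514 ± 48.9 in ga-1 mock and 62.9 ± 13.8 in gid1 mock, a log2 difference of -3.05 (adjusted p = 3.6e-06). For both genes the 3 gid1 mock arrays lay below the 3 ga-1 mock arrays. GID1C (AT5G27320) did not differ by more than the spread between replicates, with 101 ± 22.5 in ga-1 mock and 125 ± 39.8 in gid1 mock (log2 difference 0.29, adjusted p = 0.99). Where its probes lie relative to the insertion was not examined, so the GID1C value does not check the labels. GA1, the gene mutated in ga-1, was not analysed here because no probe set is paired with it in the names table used.

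**Figure D1:**
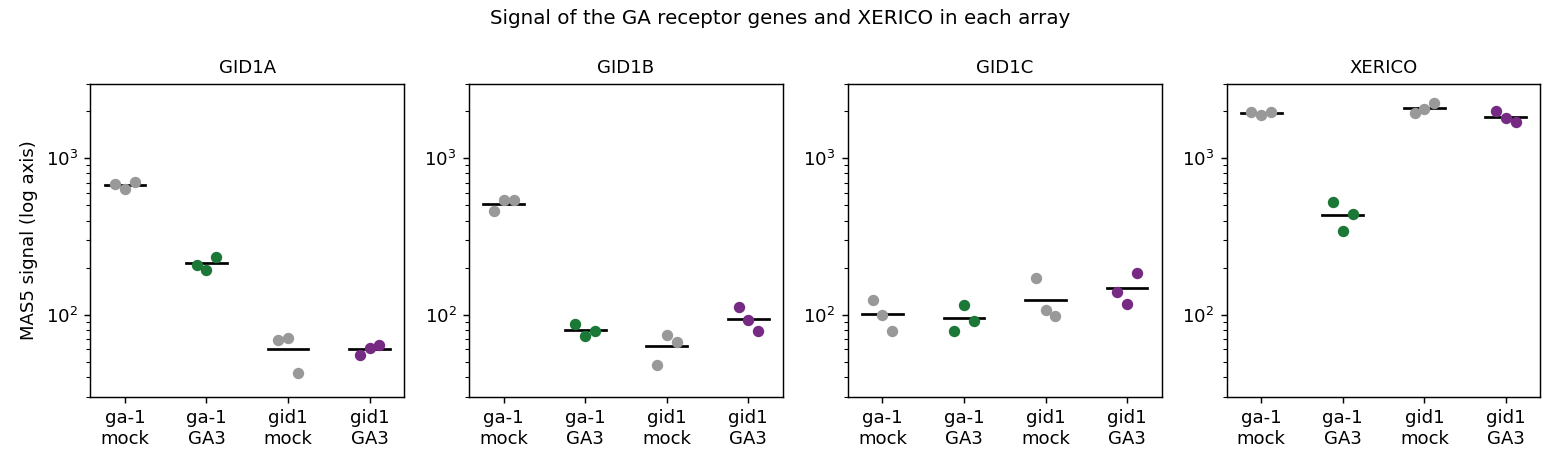
MAS5 signal on a log axis for GID1A, GID1B, GID1C and XERICO, with 1 point per array and a black line at the group mean of 3 arrays. GID1A and GID1B sit at means of 679 and 514 in ga-1 mock and at 213 and 80.0 in ga-1 with GA3, while the 4 group means of GID1C lie between 94.8 and 147.

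The first comparison asked which genes respond to GA3 within 1 h in a mutant impaired in making GA, and most of the genes called went down. XERICO (AT2G04240), a RING-type gene known to be raised by the DELLA repressors of GA signalling, fell from 1943 ± 56.9 to 436 ± 93.1 (SD, n = 3), a log2 change of -2.18 (adjusted p = 2.0e-07). The receptor genes GID1B and GID1A fell to 80.0 ± 7.20 and 213 ± 20.97, log2 changes of -2.68 (adjusted p = 9.8e-06) and -1.68 (adjusted p = 0.00059). SLY1 (AT4G24210), the F-box protein that targets DELLA proteins for degradation, fell from 919 ± 29.9 to 418 ± 69.9, a log2 change of -1.15 (adjusted p = 0.0042). The largest fall on the array, 19.3-fold, was that of an unnamed probe set, from 3591 ± 186 to 186 ± 9.12.

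In all, limma called 129 of 15922 probe sets at an adjusted p under 0.05, of which 109 fell and 20 rose. In each of the 129 the 3 arrays of one group did not overlap the 3 of the other, which 10% of probe sets would show by chance. As the 129 were selected on these arrays, this is not independent of the calls. Of the 129, 67 changed at least 2-fold, 62 of them downward. Only 55 of the 129 could be named, 49 that fell and 6 that rose. Other named genes with the largest falls were AT1G17830 (log2 change -2.43), AT4G16447 (-1.93), AT1G29270 (-1.66), AT1G21060 (-1.59), AT3G60290 (-1.53), the calmodulin-binding family gene IQD22 (-1.52) and TRM28 (-1.52), with adjusted p between 0.0025 for IQD22 and 0.036 for AT1G29270. The transcription factor gene BZIP61 (AT3G58120) rose most among named genes, from 153 ± 30.1 to 460 ± 153 (log2 change 1.55, adjusted p = 0.0068). AT1G78170 (0.98), AT5G65300 (0.92), AT5G48900 (0.84), AT5G12050 (0.75) and AT5G45670 (0.66) also rose, with adjusted p between 0.013 and 0.044. Over the alternatives run for single genes, the calls of AT5G65300 (10 of 15), AT1G29270 (9 of 16), AT5G12050 and AT5G45670 (8 of 16 each) and AT5G48900 (6 of 16) were lost most often, while those of XERICO, GID1A, GID1B, SLY1, IQD22 and AT3G60290 were not lost. Among other unnamed probe sets, the largest fall was a log2 change of -3.66, and the largest rises were log2 changes of 1.18 and 1.11.

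Gene groups fixed before the data were examined were only partly measured. Of 12 genes of GA perception and signalling, 6 were tested and 3 fell (GID1A, GID1B and SLY1), over all genes and adjusted over the list alone. Of 12 genes known as raised by DELLA proteins, 5 were tested and 3 fell (GID1A, GID1B and XERICO), and all 5 fell when adjusted over the list alone. The other members were AT5G50915 (log2 change -0.78, adjusted p = 0.056 over all genes) and AT2G31730. These lists share GID1A and GID1B. Both lists shifted down by camera, and both calls held with an estimated correlation (adjusted p = 0.0012 and 0.00013). No member of the other lists with at least 3 tested genes passed the threshold over all genes, namely 3 GASA genes, 7 expansins, 5 xyloglucan endotransglucosylase (XTH) genes, 3 auxin early-response genes and 3 root markers. Among them, EXPA8 was measured at 57.1 ± 22.8 in mock and 102 ± 20.8 with GA3 (adjusted p = 0.56), and GH3.3, an auxin-conjugating enzyme gene, at 1001 ± 152 and 1464 ± 189 (adjusted p = 0.53). Adjusted over the list alone, 2 of the 3 auxin genes rose, and camera did not call that list (adjusted p = 0.089). None of the 14 tested genes of the 11 lists with 1 or 2 tested genes was called over all genes in any comparison, and 8 lists had no tested gene. The count of calls depended on the ga-1 mock arrays: it was 70, 66 and 70 without replicates 1, 2 and 3 of that group. It was 60 without the intensity trend in limma's prior.

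The second comparison asked whether GA3 changes transcripts in seedlings with mutations in all of the GID1 receptor genes. No probe set was called by limma in gid1, and 838 had an unadjusted p under 0.05 where 796 are expected by chance. The smallest adjusted p, 0.18, was that of AT3G02480, with 175 ± 97.3 in mock and 1970 ± 1000 (SD, n = 3) with GA3 (log2 difference 3.52). The seed storage protein gene PAP85 (AT3G22640) stood at 32.7 ± 12.7 and 220 ± 98.2 (log2 difference 2.72, adjusted p = 0.82). The next named genes by p on the higher side, AT5G27820, AT1G23720 and AT5G45320, and on the lower side, AT1G51160, AT3G12010, AT3G26510 and AT1G14180, each had an adjusted p of 0.94. AT5G12050 was lower with GA3, 611 ± 68.9 against 1102 ± 182 (log2 difference -0.84, adjusted p = 0.37), and missed the threshold. Of the 7 gene lists with at least 3 tested genes, camera called none, and no member was called over all genes. Adjusted over the list alone, 1 of the 3 auxin genes fell. HAT2, the 1 tested gene of the growth and shade list, had a log2 difference of -0.61 (adjusted p = 0.94 over all genes), and with 1 gene its list allows no adjustment. Without gid1 mock replicate 1 the count of calls was 1.

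The arrays of gid1 with GA3 also stood apart in seed markers. The mean log2 value of 16 seed and early-germination genes, a list drawn up after a seed signal had been noticed, lay between 5.38 and 6.49 in the 3 gid1 arrays with GA3 and between 3.58 and 4.23 in the 3 gid1 mock arrays. It was 5.87 in ga-1 mock replicate 2 and between 3.40 and 4.48 in the other ga-1 arrays. The median log2 difference of these genes between gid1 groups was 1.98 (fry adjusted p = 0.033 over 4 set tests). An exact permutation test of the mean per array gave p = 0.1, two-sided, the smallest that 3 against 3 arrays can give. Of the 16 genes, 5 passed the low-value filter. A fit of the gid1 groups alone called 5 probe sets, all higher with GA3, of which the named ones were AT3G02480 and the seed-reserve enzyme gene ICL.

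**Figure D2:**
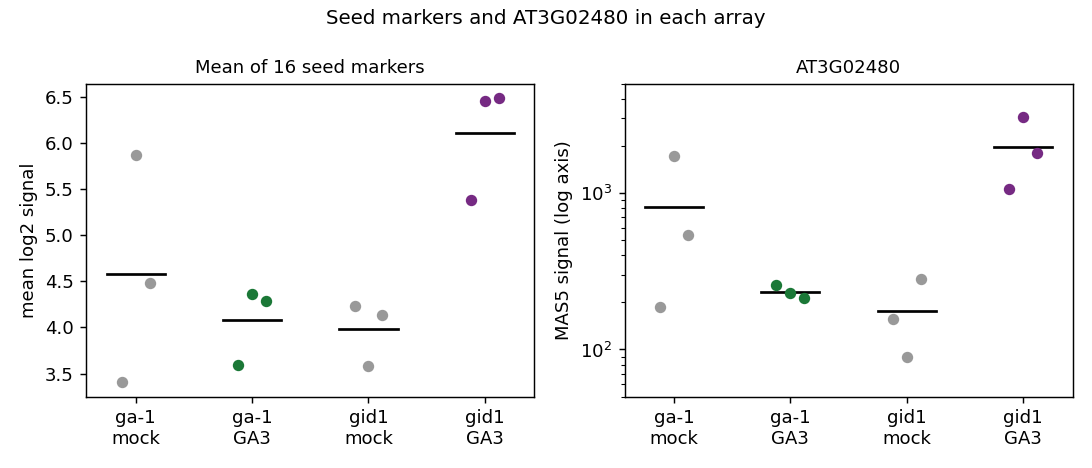
Mean log2 signal of 16 seed markers and MAS5 signal of AT3G02480 on a log axis, with 1 point per array and a black line at the group mean of 3 arrays. In both plots the 3 gid1 arrays with GA3 lie above the 3 gid1 mock arrays, and ga-1 mock replicate 2, with 5.87 and 1714, lies above the other arrays of its group.

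The third comparison set the responses of the mutants against each other. The 109 probe sets that fell in ga-1 had a median log2 change of -1.12 there and -0.03 in gid1, where 58 of them (53.2%) had a negative sign (fry adjusted p = 0.43 over 2 set tests). Their mean log2 value changed by -1.30 in ga-1 and by -0.02 in gid1, the latter with an exact permutation p of 0.6 (two-sided, smallest possible 0.1). The 20 that rose in ga-1 had a median log2 change of 0.85 there and -0.13 in gid1, where 5 of them (25%) had a positive sign (fry adjusted p = 0.22). Their mean log2 value changed by 0.89 in ga-1 and by -0.16 in gid1, the latter with an exact permutation p of 0.2. Since these sets were chosen by their change in ga-1, their ga-1 values are not independent evidence of its size. Tested gene by gene, the difference of the responses was called for 35 probe sets, 31 of which were also called in ga-1, 27 that fell and 4 that rose. The ga-1 arrays enter both tests, so this overlap is not independent.

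Named genes with a called difference included GID1B (log2 difference of responses -3.28, adjusted p = 0.00012), XERICO (-2.01, adjusted p = 0.00012), the protein kinase gene AT5G40540 (-1.45, adjusted p = 0.00088) and AT5G12050 (1.59, adjusted p = 0.0032). AT4G16447 (-2.42), IQD22 (-1.75), TRM28 (-1.72), GID1A (-1.70), UGT76E11 (-1.23) and BZIP61 (1.91) had adjusted p between 0.029 and 0.047. Over the alternatives run for single genes, these calls were lost for TRM28 in 16 of 20, UGT76E11 in 15 of 21, AT4G16447 in 14 of 21, BZIP61 in 13 of 21, IQD22 in 11 of 21 and GID1A in 10 of 20, those of AT5G12050 and AT5G40540 in 1 of 21 each, and those of GID1B and XERICO in none. AT3G02480 (-4.77, adjusted p = 0.018) was called in the difference (lost in 5 of 21 alternatives) and, in the fit of all 4 groups, in neither mutant, though the fit of the gid1 groups alone called it there. XERICO illustrates the size, with 2085 ± 154 in gid1 mock and 1850 ± 152 in gid1 with GA3. GID1A and GID1B were already low in gid1 mock. The GA perception list had 2 genes called as negative (3 adjusted over the list alone) and the DELLA list 3 (4 adjusted over the list alone), and both were called by camera (adjusted p = 0.0046 and 0.00026 with an estimated correlation). GID1A and GID1B are the called genes of the GA perception list and, with XERICO, those of the DELLA list, and the lists were not tested without GID1A and GID1B. The other tested genes of the GA perception list had log2 differences of -0.95 (SLY1, adjusted p = 0.24), -0.34 (GID1C), 0.10 (SLY2) and 0.06 (SPY). Those of the DELLA list had -1.26 (AT5G50915, adjusted p = 0.053) and -0.25 (AT2G31730). In the XTH list 1 gene was called as positive adjusted over the list alone. In the auxin list the 3 tested genes had a median log2 difference of 0.62 and were called as a set by camera (adjusted p = 0.0039, and 0.049 with an estimated correlation), with no gene called singly. Their mean log2 change was 0.35 in ga-1 and -0.24 in gid1, so both mutants enter this difference. Camera called the list in neither mutant alone (adjusted p = 0.089 in ga-1 and 0.093 in gid1). The count of 35 was 12 without the intensity trend and 8 with the seed-marker mean as a covariate, an alternative chosen after seeing the data, and 7 of these 8 were among the 35. It was 17 and 22 without ga-1 mock replicates 2 and 3, 21 and 65 without ga-1 GA3 replicates 1 and 3, 20 without gid1 mock replicate 1, and 19 and 20 without gid1 GA3 replicates 2 and 3.

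**Figure D3:**
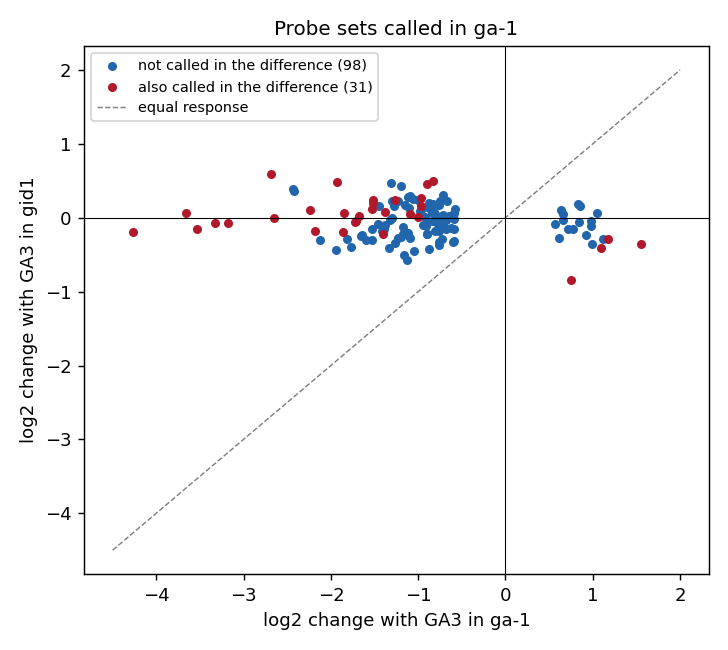
Log2 change with GA3 in gid1 (vertical) against that in ga-1 (horizontal) for the 129 probe sets called in ga-1, with 1 point per probe set. Most points lie along the horizontal zero line and away from the dashed line of equal response. Some lie between these lines, such as SPCH with -1.05 in ga-1 and -0.45 in gid1. Of the 129 points, 31, in red, had a called difference of responses.

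Few probe sets were called between the mock-treated mutants. Only 3 probe sets were called between gid1 and ga-1 without GA3, all lower in gid1, namely GID1A, GID1B and an unnamed probe set, with 257 ± 65.9 in ga-1 and 28.7 ± 25.3 in gid1 (adjusted p = 0.015). At an unadjusted p under 0.05 there were 729 probe sets, where 796 are expected by chance. XERICO stood at 1943 ± 56.9 and 2085 ± 154 in the mock groups (adjusted p = 0.99). The GA perception list and the DELLA list were called as lower in gid1 by camera (adjusted p = 0.022 for each with an estimated correlation), but their median log2 differences were positive, 0.12 and 0.10. The means were negative, -0.93 and -1.15, and GID1A and GID1B were the called members of both lists. Adjusted over the list alone, 2 genes of each list were lower and 1 of the DELLA list was higher. The stricter low-value filter left none of the 3 to be tested, so the count was 0 there, and the count was 5 without gid1 mock replicate 2.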

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

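The relabelings and splits of arrays were planned before their results were seen. The tests of low signal in gid1, of noise, of treatment and of seed tissue, with the adjustment of the fry tests, were chosen only after the results they bear on were seen.

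The responses to GA3 differed between the mutants for 35 probe sets by the test of the difference itself. Among 100 relabelings of GA3 and mock within each mutant, the real one included, 7 called as many, with up to 57 in another, so chance is not excluded for the count. Of the 6 others, 5 kept the ga-1 arrays in their real groups, so that the ga-1 response was still present in them, and 1 of the 89 that mixed the ga-1 arrays reached 44. For the ga-1 response, 129 probe sets were called against at most 2 in the other 9 of 10 splits, for gid1 0 against at most 1 (10 of the 10 splits reach 0), and for the mock mutants 3 against at most 0. These 10 splits are too few for a share under 0.05. The real split was the 1 that reached the count in ga-1 and the 1 that did so between the mock mutants.

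The differences of named genes (log2, ga-1 response minus gid1 response) were -4.77 for AT3G02480, -3.28 for GID1B, -2.42 for AT4G16447, -2.01 for XERICO, -1.75 for IQD22, -1.72 for TRM28, -1.70 for GID1A, -1.45 for AT5G40540, -1.23 for UGT76E11, 1.59 for AT5G12050 and 1.91 for BZIP61.

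For the missing response in gid1, a first technical explanation is that the signal was already low there. It holds for GID1A, whose gid1 mock level minus the ga-1 GA3 level was -1.84 ± 0.22 (SE) on the log2 scale. It also holds for GID1B, at -0.37 ± 0.24 (SE), which is within 2 SE of no difference. GID1B stood at 62.9 ± 13.8 in gid1 mock and 94.5 ± 16.9 (SD, n = 3) in gid1 with GA3 (log2 difference 0.60, limma adjusted p = 0.94). The called differences of GID1A and GID1B may thus reflect the mutations themselves. The gid1 mock level was also set against the ga-1 GA3 level for the other 29 probe sets called in both tests. In 28 of them it lay over 2 SE away, on the side of ga-1 mock. For those that fell in ga-1, this argues against a signal already low in gid1. The 29 include the 4 that rose in ga-1, for which a low signal would not explain a missing rise. All 29 were selected partly on the ga-1 GA3 arrays, so their distance from that level is not independent of the calls. Noise in the gid1 arrays is also argued against, since the lowest of the 9 differences between a GA3 and a mock array in the mean of the 109 genes was -0.0856, against a change of -1.30 in ga-1. What stays open is whether the gid1 arrays labelled GA3 were treated. This cannot be told apart from a need for the receptors. In the fit of all 4 groups, 0 probe sets were called between these groups. Of the 5 called in the fit of the gid1 groups alone, AT3G02480 and ICL are open to the explanation by seed tissue given next. The other 3 are unnamed, with log2 differences of 9.68, 5.48 and 3.93 (adjusted p = 4.4e-06, adjusted p = 1.2e-05 and adjusted p = 0.047). In the fit of all 4 groups their limma adjusted p were 0.82, 0.37 and 0.94. The probe set with 5.48 stood at 1059 ± 1311 (SD, n = 3) in ga-1 mock, so it was also high there without GA3, with a wide spread. Whether these 3 follow the seed markers or the treatment was not tested.

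AT3G02480 and PAP85 were higher in gid1 with GA3, and a candidate explanation is seed or ungerminated tissue among the sampled seedlings. The 12 markers not seen when the marker list was written had a median log2 difference of 1.93 in gid1 (fry adjusted p = 0.033), though all had been looked at before the test and only 1 of the 12 passed the low-value filter; in gid1 with GA3 the signals were 118.1 to 301.1 for AT4G36700, that 1 gene, against 85.4 to 146.7 in gid1 mock, and 253.9 to 752 for ICL, a marker seen before. The 12 markers did not move alike. In gid1 10 of them were higher with GA3, by log2 differences from 0.32 (AtLEA4-1) to 4.83 (LEA18). AT2G18540 (-0.13) and AT1G03890 (-1.31) were lower. Within groups AT3G02480 varied with the mean of these 12 markers (r = 0.82, permutation p = 0.036, and Spearman's rho = 0.69, p = 0.046, over 12 arrays), but r was 0.51 without 2 ga-1 mock arrays, so the relation rests largely on these arrays. A rise of seed genes with GA3 that needs no receptor could also appear in ga-1, but none was seen there. In ga-1 5 of the 16 markers were higher with GA3, and their median was -0.57 (fry adjusted p = 0.69). The ga-1 mock arrays spread widely, with a marker mean of 5.87 in replicate 2, so such a rise is not excluded and stays open. With the marker mean as a covariate the log2 difference of responses of AT3G02480 went from -4.77 ± 0.80 (SE) to -1.75 ± 0.63 and its call ended. The marker mean follows the gid1 treatment, so this cannot tell seed tissue from a rise that needs no receptor.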

How the results depend on the processing

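The covariate of seed markers was chosen after seeing the data and all other alternatives before. The direction of each named gene called in ga-1, in the difference or between the mock mutants was kept under every alternative run for single genes, but 56 of 267 values in ga-1 and 86 of 228 in the difference lost the threshold. These values leave out the 2-fold limit and the adjusted p under 0.01. In ga-1 11 of 17 named genes lost it in 1 to 10 alternatives, and in the difference 9 of 11 lost it in 1 to 16, with GID1B and XERICO the exceptions. The ga-1 count of 129 became 60 without trend, 67 with a 2-fold limit and 57 at an adjusted p under 0.01, and 66 to 102 with 1 array left out. The difference count of 35 became 12 without trend, 15 at an adjusted p under 0.01, 8 with the covariate and 17 to 65 with 1 array left out. With the covariate the median size of the 35 differences was 1.73 against 1.70, but the median SE was 0.41 against 0.28, since the markers follow the gid1 treatment. The gid1 count of 0 became 5 with the compared groups alone and 0 to 1 with 1 array left out. The mock count of 3 became 0 with the stricter filter, which removed all 3 from the test, and 2 to 5 with 1 array left out. For the difference, the fit of the compared groups alone is the full fit. The median in gid1 of genes that fell in ga-1 was -0.0324, 0.0640 with the covariate, and -0.0710 to 0.0189 with 1 array left out. Except where stated, the cause was not tested. The 28 list medians gave 240 values over the alternatives. Of these values 224 moved by less than the replicate spread and 16 did not. Low signals limit the seed markers, of which 5 of 16 passed the filter.

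With the replicate number as a block, the counts were 107 in ga-1, 1 in gid1, 30 in the difference and 2 between mock mutants, and the median was -0.00111. No pairing of the arrays by number was detected. With group means removed, correlations of same-number arrays from different groups ran from -0.12 to 0.11. By the same measure, 2 of 12 arrays correlated best with their own number.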

Other observations

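The genes in the next paragraph and the test of linkage were chosen only after values were seen.

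Among further named genes that fell in ga-1 were several of the bHLH class of transcription factors. SPCH, which starts the stomatal lineage, had a log2 change of -1.05 (adjusted p = 0.042). LHW, a vascular development gene, had -0.76 (adjusted p = 0.024), ATMYC1 had -0.67 (adjusted p = 0.038) and NAI1 had -0.86 (adjusted p = 0.038). Their differences from the gid1 response were not called, with adjusted p of 0.79 for SPCH, 0.12 for LHW, 0.11 for ATMYC1 and 0.22 for NAI1. No enrichment of this class was tested.

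Over both treatments together, 88 probe sets differed between the mutants, 52 of them also called in the ga-1 response. The other 36, of which 18 could be named, were lower in gid1 for 21 and higher for 15. AT4G33720 had mean signals of 477 and 487 in ga-1 mock and GA3 and of 95.03 and 117 in gid1 (log2 difference -2.07, adjusted p = 0.0084). BIM1, a brassinosteroid-signalling bHLH gene, had a log2 difference of -0.55 (adjusted p = 0.046). Several of these differ mainly with GA3, and 11 of the 18 differed in the same direction in each treatment at an unadjusted limma p under 0.05. A hypothesis of linked background near the mutated loci was tested on these 11. Within 500 genes of GID1A, GID1B, GID1C or GA1 lay 1 of 11 (9.09%), against 11.8% of other tested loci (one-sided Fisher's exact p = 0.75), and the upper exact 95% bound of 41.28% argues against such linkage as the cause of most of them. Over all 18 named loci it was 2 of 18 (Fisher's exact p = 0.64, upper bound 34.7%). Near the GID1 genes alone, and with a window of 300 genes, Fisher's exact p lay between 0.41 and 0.83 in the 6 other forms run. The bound was chosen as the criterion after a result with 300 genes had been seen, and the 11 loci after the result for all 18 and their values in each treatment had been seen. Linkage over wider regions was not tested, and the unnamed probe sets could not be placed.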
